A study of Mus musculus with 4 samples.

How the data were processed

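RNA was measured in mandibular dental arches, the tooth-bearing part of the lower jaw, of mouse embryos at embryonic day 17.5. The labels give 2 libraries from Ascl5 wild-type embryos (libraries 15 and 20) and 2 from embryos homozygous for an Ascl5 variant (libraries 18 and 14). These numbers are sample codes. They are not shared between genotypes, so libraries were not paired. Nothing in the labels says more than that the libraries are separate samples, so p-values measure the spread between these samples, which may be partly technical. Per the labels, RNA was extracted by column, and polyadenylated RNA libraries were made with a kit that keeps strand. Per the series' design text they were sequenced on a NovaSeq instrument.

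The deposited table holds 1 signal value per gene and library, which is a normalized count and not a raw count. Per the submitters' processing notes, DESeq2 and genome build mm10 were used, with no version, and the series' design text names a differential expression program of Illumina. The aligner, the counting program, its strand setting and the gene annotation are not given in the sources used here. The deposited normalized counts sum to between 22134483 and 22578580 per library. Only 32.0% to 34.6% of the values above 0 are whole multiples, within 0.1 of a read, of the commonest low value in their library, so whole reads were not recovered. If that low value stands for 1 read, the libraries hold about 21244402 reads (wild type 15), 22878309 (wild type 20), 23699265 (mutant 18) and 21827372 (mutant 14). Because antisense and near-identical genes could share reads in the authors' counting, values of such genes are uncertain.

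The test planned before the data were examined was a count model for raw counts, with limma on log values as the stated fallback for normalized ones. The fallback was used. Values were transformed to log2(value + 0.5), genes with a mean of at least 1 over the 4 libraries were kept (17979 of 24972 rows; 5583 rows are at 0 in every library), and genotype was fitted with limma 3.58.1 in R 4.3.3 with a mean-variance trend and moderated variances. Fold changes are mutant minus wild type on that log2 scale, which understates changes of low genes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. With 2 libraries against 2, an exact two-sided permutation test of 1 gene cannot give a p under 0.333, so all gene tests rest on variance shared across genes.

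Before the data were examined, 38 lists of genes (pathways, tooth and jaw tissues, and markers of other cell types) were fixed. The 37 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over all 37, and again with an estimated correlation and with fry. The list of mitochondrially encoded genes matched no row. Named genes also followed a rule fixed then: Ascl5, 18 sentinel genes, the called genes with the largest changes in each direction, leaving out predicted and clone-type names such as Gm with digits, and up to 4 members with the smallest p of each list that passed. Called genes outside the rule were named after their values were seen, and some genes that the rule takes are not reported here. Gene symbols were matched to the RefSeq annotation of GRCm38, the assembly that mm10 denotes, for coordinates and older symbols.

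On simulated data with the real gene means and relative depths and a common spread of 11.8% between libraries, the fit of mutant against wild type (17782 genes tested) called 90% of 50 genes changed 2-fold, 98% of 50 changed 4-fold and 100% of those changed 8-fold or 16-fold, with 10 false calls among 204. The changed genes were drawn only from those with a mean of at least 50, so recovery of lower genes was not simulated. In simulated data with no list changed, 0 of 37 lists were called. These simulations gave all genes the same spread and no correlation between genes, both kinder than real tissue. Alternatives covered the scaling, filter, pseudocount, variance shrinkage, weights, thresholds and each library left out. The libraries were checked for duplicates by a chi-square of approximate reads, which exceeded its degrees of freedom at least 17.3 times in every pair.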

Results

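The Ascl5 gene encodes a basic helix-loop-helix transcription factor, and the series asks how a variant of it alters gene expression in the developing lower jaw. Mandibular dental arches of embryonic day 17.5 were compared between 2 wild-type libraries (15 and 20) and 2 libraries homozygous for the variant (18 and 14, called mutant here). The normalized counts summed to 22352722 and 22578580 in wild-type libraries 15 and 20 and to 22506528 and 22134483 in mutant libraries 18 and 14. Values are normalized counts, given as mean ± SD (n = 2 per genotype) or per library, and fold changes are mutant over wild type.

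Ascl5 itself (chromosome 1, 136050804 to 136051370, GRCm38) had 21.8 and 37.3 normalized counts in wild-type libraries 15 and 20, and 10.6 and 12.1 in mutant libraries 18 and 14. Both mutant values lay below both wild-type values. The log2 fold change was -1.29 (SE 0.48) and did not pass the threshold (limma, adjusted p = 0.9999). The labels do not say what the variant does to the transcript, so this level does not check them.

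Of 17979 genes tested with limma, 2 passed the threshold. Neither call was kept with any 1 library left out, in fits with 1 residual degree of freedom, while the log2 fold change of Dlx1as stayed between -4.30 and -3.53. The Dlx1as call also ended with no filter (adjusted p = 0.0558) and, in settings chosen after the data were seen, with vooma weights (0.264) and with sex of the embryo as a covariate (0.482). Dlx1as, an antisense RNA at the Dlx1 locus (chromosome 2, 71530638 to 71537891), fell from 390 and 665 normalized counts in the wild-type libraries to 35.2 and 31.5 in the mutant libraries (log2 fold change -3.92, SE 0.30, adjusted p = 0.0153). It overlaps Dlx1, and the strand setting of the authors' counting is not given, so its value is uncertain. Gm13304, a copy of the chemokine gene Ccl21 named after its value was seen, was listed at 0 in both wild-type libraries and at 317 and 338 in the mutant libraries (limma, adjusted p = 0.00208). Other Ccl21 copies were filled instead in wild type, Gm21541 at 265 in library 15 and Ccl21c at 357 in library 20. The copies summed to 311 ± 65.1 in wild type and 327 ± 14.98 in mutant. At an unadjusted p under 0.05 there were 768 genes, 561 higher and 207 lower in mutant, where chance alone gives 899. The share of genes whose genotypes did not overlap was 27.4%, and chance gives 33.3%. Leaving out wild-type library 15, mutant 18 or mutant 14 left 0 calls (538, 1209 and 446 genes at an unadjusted p under 0.05), and leaving out wild-type 20 gave 5, namely Xist, Ddx3y, Eif2s3y, Kdm5d and Uty.

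**Figure D1:**
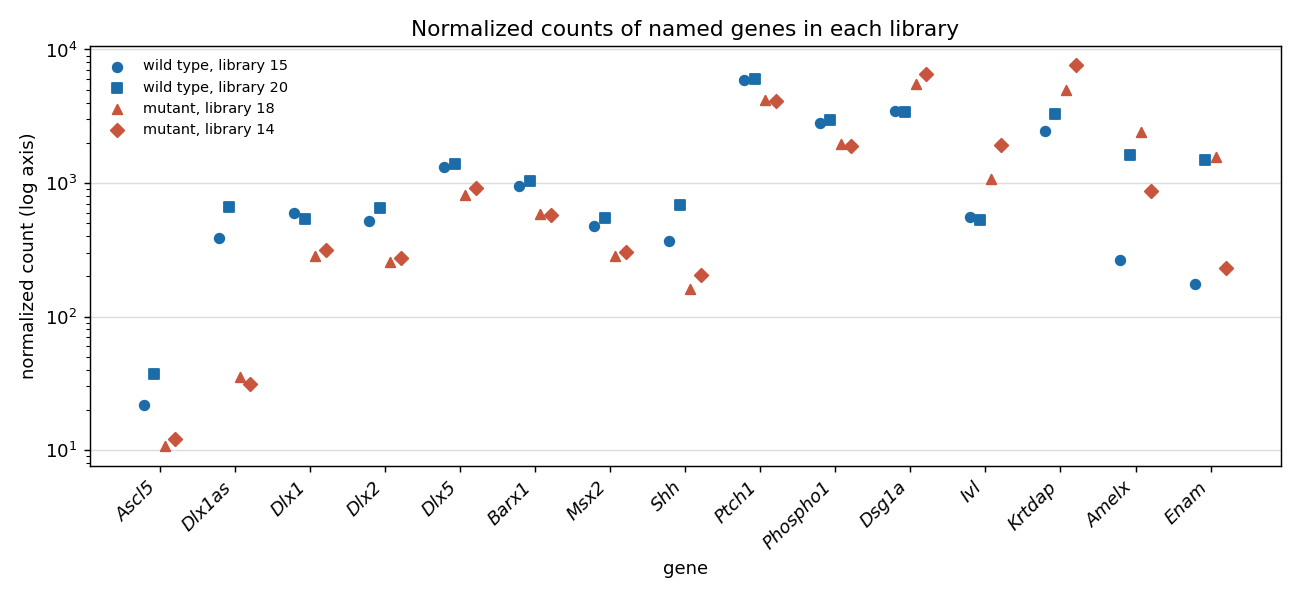
Normalized counts (log axis) of 15 named genes in each of the 4 libraries, with wild type in blue and mutant in red and 1 point per library. Dlx1as lies at 390 and 665 in wild type and 35.2 and 31.5 in mutant, while Amelx and Enam overlap between genotypes.

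The genotype did not coincide with the main differences between libraries. Mutant library 14 stood apart on the first principal component (41.9% of the variance), at 71.2 against -13.6 for mutant 18, -17.7 for wild type 15 and -39.9 for wild type 20. Wild-type library 20 and mutant 18 were the most alike pair (Pearson 0.979 across genes, which are not replicates), above the 2 wild-type libraries (0.973) and the 2 mutant libraries (0.972). Xist, the RNA of the inactive X chromosome, was at 38619 in wild-type library 15 and at 12.7, 7.64 and 5.005 in libraries 20, 18 and 14. Ddx3y, on the Y chromosome, was listed at 0 in library 15 and at 2490, 3027 and 2382 in the other libraries. Sex therefore differed between the genotypes as sampled.

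Of the 37 gene lists, 18 passed with camera at the preset correlation, 8 higher and 10 lower in mutant. None passed with an estimated correlation or with fry. Some lists share members, so their calls are not independent. Shh, Fgf3 and Msx2 are in enamel knot signalling and also in other tooth or pathway lists. Among the individual members named below, Dlx1as and Gm13304 apart, none passed over all genes, so their values are given as measured.

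Dental mesenchyme genes, the transcription factors and signals of the tissue under the tooth epithelium, lay lower as a list in mutant (16 of 24 members lower, 12 with no overlap between genotypes, median log2 fold change -0.26, adjusted p = 2.26e-07). Adjusted over the list alone 7 members passed, all lower, and over all genes 0 did. With an estimated correlation the adjusted p was 0.456. Dlx2 was at 589 ± 92.9 in wild type and 264 ± 11.6 in mutant, Dlx1 at 565 ± 40.6 and 300 ± 24.5, Barx1 at 993 ± 53.2 and 584 ± 6.52, and Dlx5 at 1344 ± 50.5 and 866 ± 69.0. The sentinel Msx1 was at 1701 ± 422 and 1352 ± 55.8.

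Signalling lists lay lower as well. In the Hedgehog pathway 13 of 15 members were lower (median -0.13, adjusted p = 3.59e-06), with 4 lower adjusted over the list alone. The ligand Shh was at 371 and 684 in wild type and 161 and 205 in mutant, its receptor Ptch1 at 5946 ± 98.4 and 4125 ± 36.1, its target Gli1 at 2550 ± 134 and 1800 ± 261, and Ihh at 230 ± 11.3 and 127 ± 42.3. The BMP and TGF-beta list had 23 of 26 members lower (median -0.13, adjusted p = 4.16e-05, 0 adjusted over the list alone), where Inhba (log2 fold change -0.40), Tgfb1 (-0.37), Bmp5 (-0.38) and Nog (-0.44) had the smallest p. The FGF list had 17 of 20 lower (median -0.13, adjusted p = 0.00199, 0 adjusted over the list alone). Fgf3 was at 12.3 and 29.1 in wild type and 1.91 and 0 in mutant, Etv4 at 298 ± 32.5 and 169 ± 50.2, and Fgf4 had a log2 fold change of -1.04, while Fgf7 was at 329 ± 21.5 and 397 ± 14.1. With an estimated correlation the adjusted p was 0.456 for these 3 lists. The FGF call was lost without wild-type library 15 (median -0.028) or mutant 18 (median -0.076, adjusted p = 0.255), and its median was -0.20 without wild-type 20 and -0.27 without mutant 14. The BMP and TGF-beta median was -0.08 without wild-type 15, and the Hedgehog median -0.21 without wild-type 20 and -0.20 without mutant 14.

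Dental epithelium and stem cell genes passed as lower (16 of 25 members, median -0.12, adjusted p = 0.00527, 2 lower adjusted over the list alone), as did enamel knot signalling, the signals of the tooth's organizing centre (12 of 20 lower, median -0.11, adjusted p = 0.0108, 3 lower and 1 higher adjusted over the list alone). The adjusted p with an estimated correlation was 0.575 and 0.539. Both calls were lost without wild-type library 20, where the medians stayed at -0.095 and -0.153 (adjusted p = 0.0894 and 0.167), and without mutant 18 (adjusted p = 0.903 and 0.405). Without mutant 18 the dental epithelium median was -0.015, with the test's direction turned to higher, and the enamel knot median turned to 0.085, with the test's direction still lower; without mutant 14 the medians were -0.38 and -0.26. The enamel knot call was also lost with genes of a mean of at least 20 (adjusted p = 0.076), a filter chosen after the data were seen. Dlx3 was at 1919 ± 118 and 1382 ± 155, and Msx2 at 511 ± 54.4 and 296 ± 13.9, while Wnt3 was at 69.5 ± 18.4 and 145 ± 25.8. The sentinel Sp6 overlapped between genotypes (1684 ± 433 and 1195 ± 345).

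Genes of mineralized and skeletal tissue lay lower as lists. Osteoblast and osteocyte markers had 18 of 21 members lower (median -0.39, adjusted p = 2.03e-09), 7 of them adjusted over the list alone. Odontoblast and dentin genes had 16 of 22 lower (median -0.30, adjusted p = 2.07e-06, 5 adjusted over the list alone), and cartilage 16 of 17 (median -0.41, adjusted p = 2.36e-09, 1 adjusted over the list alone). For all 3 the adjusted p was 0.456 with an estimated correlation. The osteoblast and odontoblast lists share members, among them Dmp1, Phospho1 and Smpd3, so they are not separate findings. The osteoblast transcription factor Sp7 was at 7398 ± 496 in wild type and 5060 ± 652 in mutant, the mineralization phosphatase Phospho1 at 2892 ± 93.3 and 1929 ± 43.9, Dmp1 at 9569 ± 526 and 5790 ± 1748, Smpd3 at 8677 ± 159 and 6114 ± 594, and Vwde at 103 ± 10.5 and 34.9 ± 17.9. Of the cartilage genes, Comp was at 817 ± 23.8 and 522 ± 28.4, and Acan, Col10a1 and Sox9 had log2 fold changes of -0.56, -0.44 and -0.38. The sentinels Col2a1 (-0.45) and Bglap (-0.39) did not pass. Library 14 was the lowest of the 4 for each of these lists. Without it the odontoblast call was lost (adjusted p = 0.0629, median -0.14) and the osteoblast median was -0.26. The cartilage means overlapped, at 10.50 and 10.08 on the log2 scale in wild-type 15 and 20 and 10.12 and 9.76 in mutant 18 and 14, and that list's median was -0.24 without wild-type 15 and -0.27 without mutant 14.

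Enamel matrix and ameloblast genes did not pass as a list (15 of 26 lower, adjusted p = 0.0512), with 2 lower adjusted over the list alone, Msx2 and Vwa2 (log2 fold change -1.14). In all, 5 members were lower with no overlap, those 2 with Dlx3, Fam20a (-0.33) and the enamel protease Klk4 (-2.31, not passing), and 4 were higher, Hopx (0.68), Fam83h (0.53), Slc24a4 (0.48) and Lama3 (0.39). Of these 9, all but Msx2 and Dlx3 were chosen after their values were seen. The sentinel matrix genes overlapped between genotypes. Amelx was at 263 and 1621 in wild-type libraries 15 and 20 and 2421 and 868 in mutant libraries 18 and 14, and Enam at 175, 1490, 1570 and 232 in the same order. Ambn (802, 2491, 1383 and 540), the protease Mmp20 (45.7, 144, 61.8 and 10.1) and the dentin gene Dspp (687, 1346, 1910 and 629) overlapped likewise.

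Keratinocyte genes of oral lining and skin lay higher in mutant (24 of 25 members, 15 with no overlap, median log2 fold change 0.59, adjusted p = 1.6e-21), and 10 passed adjusted over the list alone but 0 over all genes. With an estimated correlation the adjusted p was 0.456. The cornified envelope gene Ivl was at 542 ± 15.6 in wild type and 1495 ± 589 in mutant, the desmosomal cadherin Dsg1a at 3418 ± 54.3 and 6038 ± 773, Krtdap at 2882 ± 581 and 6271 ± 1882, and Calml3 at 1870 ± 161 and 3147 ± 509. The basal keratin Krt14 overlapped (7406 ± 3160 and 9896 ± 935). The keratinocyte median was 0.91 without mutant 18. Epithelial junction genes had 20 of 26 higher (median 0.32, adjusted p = 1.14e-06, 0 adjusted over the list alone, and adjusted p = 0.463 with an estimated correlation). The members with the smallest p were Perp (log2 fold change 0.74), Pkp3 (0.70), Pkp1 (0.62) and Dsp (0.63), each highest in mutant 14. Pkp3 was at 1022, 1045, 1330 and 2131 in libraries 15, 20, 18 and 14. The junction call was lost without mutant library 14 (median 0.062, adjusted p = 0.142), its median was 0.53 without mutant 18, and the sentinel Cdh1 was at 1987 in mutant 18 and 3298 in mutant 14 against 1973 and 1929 in wild type. Hair follicle genes passed narrowly (10 of 13 higher, median 0.40, adjusted p = 0.0377, and 0.557 with an estimated correlation) with 1 member, Msx2, lower adjusted over the list alone. Krt35, Krt31 and Hoxc13 had log2 fold changes of 0.74, 0.99 and 0.54. That call was kept in 1 of the 4 fits with a library left out, and its median was 0.19 without wild-type 20, 0.77 without mutant 14 and turned to -0.16 without mutant 18.

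Markers of other cell types also differed. All 7 melanocyte genes were higher with no overlap (median 1.44, adjusted p = 1.78e-06, 3 adjusted over the list alone), at low levels such as Pmel at 45.7 ± 0.53 and 90.3 ± 11.7, Dct at 46.9 ± 17.3 and 97.2 ± 21.6, Tyr at 8.69 ± 1.16 and 24.6 ± 3.47 and Tyrp1 at 3.06 ± 0.16 and 14.5 ± 13.8. The melanocyte median was 0.85 without mutant 14. Macrophage and mast cell genes had 15 of 16 higher (median 0.27, adjusted p = 9.19e-06, 2 adjusted over the list alone). The mast cell protease Cpa3 (0.84), Mrc1 (0.52), Mcpt4 (0.56) and Tpsb2 (0.49) had the smallest p. Mcpt4 was at 315, 495, 601 and 561 and Tpsb2 at 783, 919, 961 and 1475 in libraries 15, 20, 18 and 14. The macrophage and mast cell median was 0.17 without wild-type 15 and 0.44 without wild-type 20. Salivary gland genes (12 of 13 higher, median 3.89, adjusted p = 2.81e-09, 2 adjusted over the list alone) followed library 14, with Dcpp3 at 1.05, 0.98, 19.1 and 408 and Dcpp1 at 3.16, 0, 16.2 and 249 in libraries 15, 20, 18 and 14. Dcpp2 was listed at 0 in wild type and at 1.91 and 22.2 in mutant, and Prom2 had a log2 fold change of 0.69. The median of that list was 0.33 without library 14 and 5.50 without library 18. Neuron and Schwann cell genes (14 of 16 higher, median 0.42, adjusted p = 5.28e-05, 0 adjusted over the list alone) likewise lost their call without library 14 (median 0.049, adjusted p = 0.823) and without wild-type 20 (median 0.31, adjusted p = 0.0645), and their median was 0.68 without wild-type 15 and 0.66 without mutant 18. Elavl4 and Stmn2 had log2 fold changes of 1.20 and 0.69. Both were highest in mutant 14 (139 and 646, against 70.7 and 323 in mutant 18). With an estimated correlation the adjusted p was 0.456 for these 4 lists.

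Immediate early and heat shock genes passed at the threshold (17 of 24 higher, median 0.20, adjusted p = 0.0486, 0 adjusted over the list alone, and adjusted p = 0.670 with an estimated correlation). Hspa1b (0.75), Hspa1a (0.71) and Hspb1 (0.47) were higher, each highest in mutant 14, and Klf2 (-0.43) was lower. Hspa1a was at 232, 224, 284 and 488 in libraries 15, 20, 18 and 14. The call was lost without wild-type 20 (median 0.067), without mutant 14 (median 0.0069), with scaling to library totals (adjusted p = 0.051) and with pseudocount 0.1 (adjusted p = 0.0507), the last chosen after the data were seen. The list of replication-dependent histone genes was lower (40 of 59 members, median -0.22, adjusted p = 0.00837, 0 adjusted over the list alone, and adjusted p = 0.575 with an estimated correlation), and that call was lost without wild-type 20 (median -0.049, adjusted p = 0.939; the median was -0.62 without wild-type 15) and with genes of a mean of at least 20 (adjusted p = 0.208). The symbol pattern that made this list also took H13, H19 and H1f0, which are not such genes, and a pseudogene; without these 4, chosen after the data were seen, 36 of 55 were lower (adjusted p = 0.00939). Its named members were near the floor, as Hist1h3a at 11.2 ± 2.46 and 1.996 ± 1.49, Hist1h3b and Hist1h4m listed at 0 in mutant and at under 6 in wild type, and Hist1h4n listed at 0 in wild type.

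**Figure D2:**
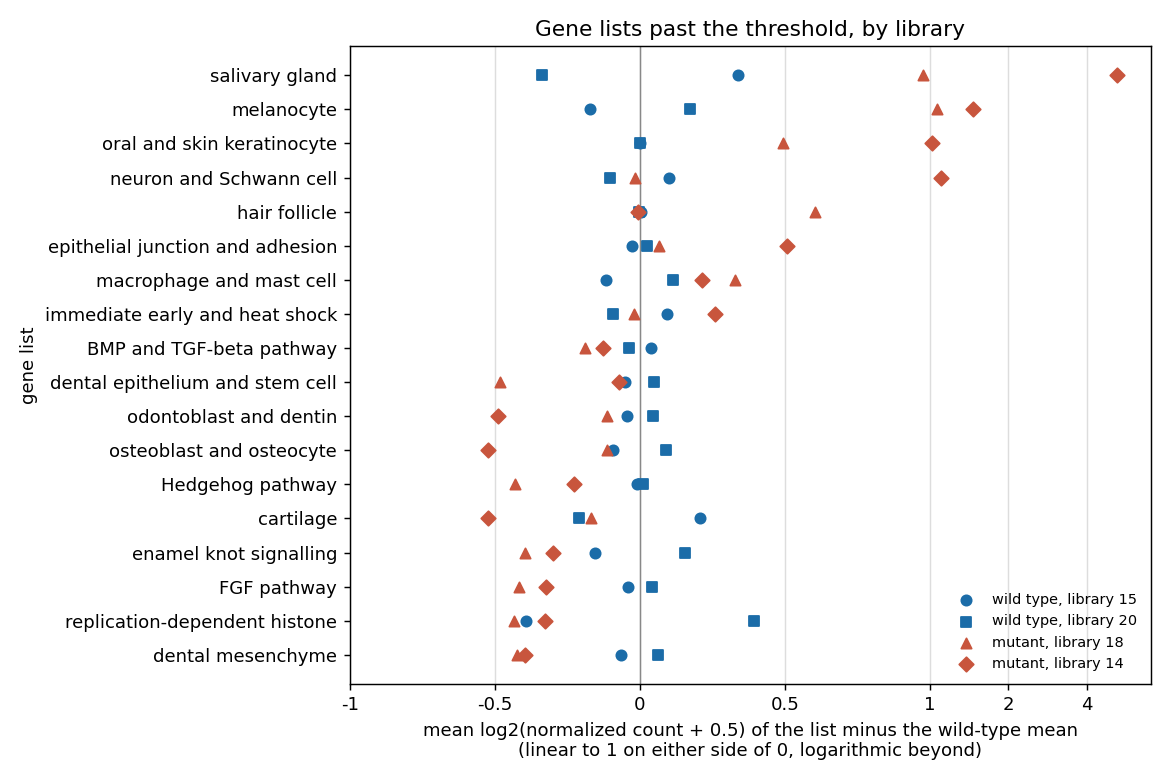
For each of the 18 lists that passed, the mean log2(normalized count + 0.5) of its tested members in each library minus the mean of the 2 wild-type libraries, with wild type in blue and mutant in red. Dental mesenchyme lies lower in both mutant libraries and keratinocyte and melanocyte genes higher, while the salivary gland and neuron lists are highest in mutant library 14.

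The other 19 tested lists did not pass. The adjusted p was 0.844 for the Wnt pathway, 0.703 for ectodysplasin and NF-kB, 0.338 for mesenchymal transition, 0.818 for class I and II bHLH factors, 0.217 for the cell cycle, 0.102 for p53 and apoptosis, 0.144 for hypoxia and glycolysis, 0.214 for interferon response and 0.217 for proteoglycan and collagen matrix. For cell types it was 0.248 for osteoclast, 0.381 for skeletal muscle, 0.991 for erythroid and blood, 0.0861 for endothelial, 0.0948 for neutrophil and marrow, 0.132 for adipocyte, 0.139 for smooth muscle and pericyte, 0.0505 for sex of the embryo and 0.138 for cytosolic ribosomal protein. Median and mean differed in sign for the Wnt (-0.013 and 0.032, test lower), ectodysplasin (0.0083 and -0.025, test lower) and erythroid (0.099 and -0.033, test higher) lists. The muscle gene Acta1 (30115 ± 7823 and 28161 ± 10883) and the globin Hbb-bs (13045 ± 4244 and 12573 ± 7174) overlapped.

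No called gene lay within 10 Mb of Ascl5. Of 138 tested genes there, 11 had an unadjusted p under 0.05 (7.97%), among them Ascl5 itself and Pkp1. The share was 4.25% of tested genes elsewhere (Fisher's exact test across genes, which are not replicates, two-sided p = 0.0516). Tested genes without coordinates (352) were left out.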

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

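The filters at means of 5, 10, 20 and 50, the weights, the summed gene copies, sex as a covariate, and for lists the mean of 20, both pseudocounts and the histone list without 4 members were chosen after seeing the data. DESeq2, limma-voom and the count-model likelihood ratio test were not run, since the values are not counts, and robust shrinkage was applied in limma. The count of 2 called genes became 4 with robust shrinkage, with pseudocount 1, with at least 1 CPM in every library of a genotype and a mean of 10, and at an adjusted p under 0.1 (Cyp26c1 and Sprr2a1 joined in the first 3), 1 with no filter (Gm13304), 1 with gene copies summed (Dlx1as), and 0 with vooma weights (714 genes at an unadjusted p under 0.05) or with sex as a covariate (524), which gives the fold changes of leaving out wild-type 15, the 1 female library. It ranged from 0 to 5 with each library left out, where the lone library of a genotype is assumed to vary like the other genotype. It stayed 2 under the other scalings and filters. Ascl5 kept its direction, at -1.67 to -0.91 over the libraries left out. The 18 called lists became 0 with an estimated correlation and 0 with fry, and 15 to 24 over the libraries left out. They became 16 with a mean of at least 20 (15 of the 18 kept; enamel knot signalling and histone lost, and melanocyte not tested with under 5 members left), 17 with pseudocount 0.1 and 20 with pseudocount 1, and stayed 18 with the shorter histone list. Without mutant 18, the direction of the test turned for dental epithelium and hair follicle, and the median for enamel knot signalling and hair follicle. The adjusted p of dental epithelium and hair follicle ranged from 9.89e-06 (dental epithelium) and 5.33e-06 (hair follicle), both without mutant 14, to 0.903 and 0.419. Of 82 named genes, 6 changed sign, none of them called: over the libraries left out Acta1 ranged from -0.53 to 0.28, Ambn from -1.53 to 0.11, Amelx from -0.16 to 2.46, Dspp from -0.61 to 0.99, Enam from -1.30 to 1.79 and Hbb-bs from -0.76 to 0.48. With sex as a covariate Acta1 was 0.14, Amelx -0.16, Dspp -0.30, Enam -1.30 and Hbb-bs 0.20. Why the counts moved was not tested, except that leaving out a library leaves 1 residual degree of freedom. Without wild-type 20, the wild-type library left was the female one. The genes called there were Xist, Ddx3y, Eif2s3y, Kdm5d and Uty, so those calls follow the sex of the libraries. With copies summed, the Gm13304 call was lost because the sum had a log2 fold change of 0.0885. The gene copies summed to 1 feature left out Ccl21a, whose transcript shares 82.8% of 31-base words with Gm13304. No 95% interval for reads can be given, because whole reads were not recovered.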

Other observations

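The main fit, its intervals, the fits with a library left out and the comparison of called genes and lists between splits were planned. Apart from the count of called lists between splits, their use to weigh explanations, and every other test below, was chosen after the result it bears on was seen, and the lists of cornified, basal, oral suprabasal, late tooth matrix and dental homeobox genes were also written then.

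Genes of the outer, cornified layers of skin had a median log2 fold change of 1.24 over 20 genes. They were chosen after keratin values were seen, so this describes the pattern and does not test it. Among them were Krt1 (21505 ± 6632 in wild type and 53272 ± 14234 in mutant), Krt10 and Lor. The median was 0.39 for 7 oral suprabasal genes, and the difference between these lists was not tested. Cyp26c1, an enzyme that degrades retinoic acid, was at 78.7 and 106 in wild type and 0.95 and 0 in mutant and missed the threshold (limma adjusted p = 0.0684).

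The real grouping called 2 genes and 18 lists. The other splits of the 4 libraries into 2 and 2 each called 1 gene, and they called 14 and 15 lists. So 1 of the 3 splits, the real one, reached each count. With 3 splits no share under 0.05 can be reached. With genes of a mean of at least 20, another split called 2 genes, as many as the real one. Wild-type 15 and mutant 14 against wild-type 20 and mutant 18 gave 1858 genes at an unadjusted p under 0.05, against 768 for genotype. This points to a structure of the samples other than genotype, for which the main fit had no term.

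The higher keratinocyte list does not come from mutant library 14 alone: without it the list median was 0.46 and the call was kept, and 17 of 25 members lay above both wild-type libraries in mutant 18. The kept call adds little, since the list also passed in a split that is not genotype, wild-type 15 and mutant 18 against the others (adjusted p = 0.00172). More skin and surface epithelium in the mutant dissections may account for it. Basal genes had a median of 0.186 and their library means overlapped, while cornified minus basal levels separated the genotypes (0.11 and -0.36 against 0.71 and 1.035). Dental and oral epithelium also express basal genes, and this baseline could hide added skin, but its size was not measured. Melanocyte genes, of a cell type other than keratinocytes, also lay higher (7 of 7 with no overlap), though at low levels. Hair follicle genes, also of skin, rose only in mutant 18. Their log2 means were 6.897 and 6.889 in wild-type 15 and 20, 7.497 in mutant 18 and 6.885 in mutant 14. Cornified genes were highest in mutant 14 (12.31, against 11.70 in mutant 18). Cornified minus oral suprabasal levels separated the genotypes too (1.085 and 0.785 in wild type, 1.443 and 1.951 in mutant). The cornified genes were chosen after keratin values were seen, so this tests neither explanation. More skin and a change of keratinocyte differentiation in the mutant cannot be told apart here.

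Whether the lower Dlx genes and Shh reflect a smaller share of jaw tissue beside other tissues in the mutant libraries stays open. Bone and cartilage genes had a median of -0.39 and 16 dental homeobox genes one of -0.42. Bone and cartilage means were 11.49 and 11.40 in wild-type 15 and 20, 11.32 in mutant 18 and 10.92 in mutant 14. Homeobox means were 9.25, 9.45, 8.80 and 8.97 in the same order. Both were lower in both mutant libraries, but bone and cartilage genes were lowest in mutant 14 and homeobox genes in mutant 18. The homeobox mean minus the bone and cartilage mean overlapped between genotypes. Less tooth tissue was tested with 8 late tooth matrix genes, whose mean differed by -0.504 between genotypes but overlapped (6.48 and 8.48 in wild type, 7.88 and 6.08 in mutant). These means lay further apart within each genotype than between genotypes, so the test cannot tell whether the mutant libraries held less tooth tissue.

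For single genes, assignment of shared reads is a candidate explanation of the Gm13304 call. The copies summed to a log2 fold change of 0.0885, each library filled 1 copy, and the Gm13304 and Gm21541 transcripts share 100% of 31-base words. Sprr2a1 (0 and 0 against 48.4 and 90.4) and Sprr2a2 (39.4 and 24.4 against 0 and 0) summed with Sprr2a3 to 1.11, far less than either alone, and may be of the same kind. For Dlx1as, the 95% interval reached up to -3.22, below the lower limit of -1.30 for Dlx1. Its level was 65.7% and 124% of Dlx1 in wild type and 12.5% and 9.92% in mutant. A constant share of Dlx1 reads counted on Dlx1as therefore does not account for the whole fall. A share that differs between libraries was not tested and cannot be excluded, since the ratio also differed within wild type.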
